A study of Homo sapiens with 18 samples.

How the data were processed

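The samples were 18 RNA preparations of primary human macrophages derived from CD14-positive monocytes, in 6 groups of 3 given by the titles (control or primed; 0 h, 3 h or 24 h of IFN-gamma at 100 U/ml). The arrays were Affymetrix HG-U95Av2, on which each probe set measures 1 transcript or a group of similar ones. The deposited table gave 12625 probe sets per array as intensity on a linear scale, 1 value per probe set. How the authors derived the values is not given in the sources used here. Each array's mean after trimming 2% of the probe sets at each end lay between 250.1 and 250.2, as scaling each array to a common trimmed mean gives. The array medians still ranged from 50 to 109.4, a ratio of 2.19. A ratio above 1.5 had been set as the condition for quantile normalization between arrays, which was therefore applied. Scaling and quantile normalization both assume that most genes do not differ between arrays, so a global shift of RNA content cannot be seen.

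Values below the 20th percentile of all values (15.1) were raised to it, and values were taken to log2. Differences from a group at this floor are lower bounds. After 67 Affymetrix control probe sets were left out, probe sets above the 40th percentile (45) in at least 3 arrays were kept, which left 9388 of 12558. Gene symbols came from the platform's probe annotation and were checked through gene identifiers against the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and lacked 12. Of the 12625 probe sets 10961 had 1 symbol, 545 had several and 1119 had none listed. Counts cover all tested probe sets, and named genes and lists only the 8305 tested ones with 1 symbol (6560 genes). For the 1323 genes with more than 1 tested probe set, the one with the highest mean log2 signal stood for the gene.

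A linear model with 1 mean per group was fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend, 12 residual degrees of freedom), for 10 comparisons. These were the priming effect at 0 h, the responses of control and of primed macrophages at 3 h and 24 h, 24 h against 3 h in control macrophages, primed against control macrophages at 3 h and at 24 h, and the difference of the primed and control responses at 3 h and 24 h. limma's moderated tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Pool numbers in the titles may pair samples across groups. To check this, the deviations of arrays from their group means were correlated across probe sets, which are not independent replicates: r was 0.344 to 0.466 between arrays of pool 1, 0.426 to 0.517 in pool 2 and 0.263 to 0.403 in pool 3. With pool 2 left out r was only 0.011 to 0.186 in pools 1 and 3, whose higher values come largely from pool 2 shifting the group means. With 2 arrays per group the deviations of pools 1 and 3 mirror each other. Both pools therefore give the same values, which are a single measure. Whether samples of pool 1 or of pool 3 are paired across groups is thus not settled, while pool 2 stood apart in every group. The fit with the pool as a block (10 residual degrees of freedom) is given beside the one without. Standard errors and adjusted p-values come from the fit without the block unless stated, which leaves pool differences in the residual spread. The arrays of pools 1 and 3 were kept as separate samples, as labelled.

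The comparisons, the threshold, the filter, the gene lists and the rule for named genes were chosen before the data were examined. Named genes were, in each comparison, the 12 highest and 12 lowest log2 fold changes among called genes that changed in the same direction in all 3 pools (8 and 8 for differences of responses), the 4 called members with the smallest p of each list (2 members if none was called), and 24 genes fixed by name, of which 20 were measured; the others are not analysed here. The text gives some of these.

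The 19 pathway lists were IFN-gamma receptor and JAK-STAT signalling, IFN-gamma effector genes, type I interferon-stimulated genes, MHC class I and immunoproteasome, MHC class II presentation, chemokines, migration receptors and integrins, inflammatory cytokines, Toll-like receptor and NF-kB pathway, Fc receptors and complement, scavenger receptor and M-CSF macrophage genes, sterol synthesis and uptake, cell cycle, immediate early and AP-1 genes, metalloproteinases and inhibitors, phagocyte oxidase, lysosomal genes, metallothioneins with heat shock and oxidative stress genes, and apoptosis. The 7 marker lists covered T, NK and B cells, platelets, neutrophils, erythroid and dendritic cells. Some genes stood in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with the block, adjusted over the lists within a comparison.

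The alternatives were the values as deposited, log2 of the value plus an offset in place of the floor, no filter (12558 probe sets) and a stricter filter at the 60th percentile (6462), no intensity trend, the replicate block, and each pool left out in turn. Array quality weights, and pools 1 and 3 averaged as 1 sample, were added after seeing the data. The procedure was tested on simulated data made by adding known changes to 200 of 9388 probe sets. Each change was added in full in all 3 pools, and noise was drawn independently for each probe set. Real changes can differ in size between pools and noise can be shared by probe sets. The shares recovered and the false calls hold only for this simpler setting. For the priming comparison the fit without the block recovered 10.4% of added changes of log2 size 1, 35.8% of size 2 and 71.2% of size 3, with 0 false calls, and for the difference of 24 h responses 0%, 16.4% and 21.2%. With the block it recovered 25.4%, 65.7% and 89.4% for priming, with 5 false calls among 125. For the difference of 24 h responses it then recovered 14.9%, 52.2% and 56.1%.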

Results

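RNA was measured on 18 oligonucleotide arrays hybridised with samples of primary human macrophages. CD14-positive blood monocytes had been cultured for 48 h with macrophage colony-stimulating factor (M-CSF, 10 ng/ml), the growth factor under which monocytes become macrophages. Control cultures received M-CSF alone, and primed cultures also received interferon-gamma (IFN-gamma) at 3 U/ml, a low dose of the cytokine that activates macrophages. Control and primed macrophages were then left unstimulated (0 h) or were stimulated with 100 U/ml IFN-gamma for 3 h or 24 h. No group was kept unstimulated for 3 h or 24 h. Changes from 0 h, called responses here, and changes between 3 h and 24 h therefore cannot be told apart from effects of further culture and handling. Each of the 6 groups held 3 arrays, 1 from each of pools 1, 2 and 3. The labels do not say what a pool contains, so limma's p-values for single probe sets measure only the spread between these samples, which may be technical. Camera's p-values for lists set the genes of a list against the other genes, at a preset correlation of 0.01 between genes. They depend on that setting, and very small ones are not a measure of agreement between samples. Of 84 pathway list calls, 58 stayed with an estimated correlation. The number of arrays limits the precision. Log2 fold changes are given with their standard error (SE), from 3 arrays against 3, and for the differences of responses from 12 arrays. Genes are called higher or lower at an adjusted p under 0.05 in limma.

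The arrays of pool 2 stood apart from those of pools 1 and 3 in every group. In the deposited values their medians lay between 90 and 109.4, against 50 to 63.7 in pool 1 and 57.6 to 68.8 in pool 3, while the trimmed mean of every array lay between 250.1 and 250.2. The mean signal of the 18 bacterial and phage control probe sets was 2410 to 3349 in pool 2, 131.7 to 210.5 in pool 1 and 152.5 to 250 in pool 3. The 3' to 5' signal ratio of GAPDH, a measure of RNA integrity, was 1.64 to 2.61 in pool 2, 1.18 to 1.31 in pool 1 and 1.23 to 1.36 in pool 3. With the condition as a term, limma called 3925 probe sets different between pools 1 and 2 and 3630 between pools 2 and 3. Between pools 1 and 3 limma called 0 probe sets, with 1111 of 9388 (11.8%) at an unadjusted p under 0.05. Each pool held all 6 groups. Counts are therefore given beside each comparison also with the pool as a replicate block and without each pool.

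**Figure D1:**
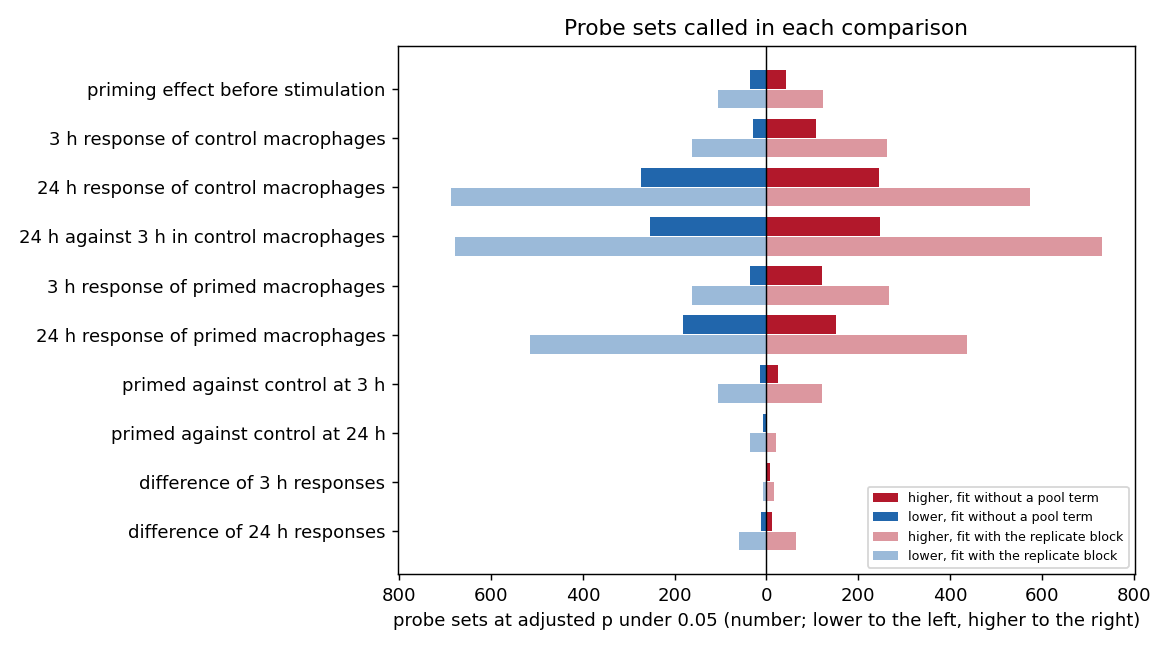
Probe sets called higher (right, red) or lower (left, blue) in each of the 10 comparisons, as numbers of probe sets, in the fit without a pool term (dark) and with the pool as a replicate block (light). The 24 h response of control macrophages had 520 called probe sets without and 1262 with the block, and primed against control at 24 h had 8 and 58.

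The first comparison asked what priming alone had changed before stimulation. Primed macrophages held far less RNA of antiviral genes that interferons induce. IFIT2, whose protein binds foreign RNA, fell by 4.54 (SE 0.46, adjusted p = 2.08e-05), a 23.3-fold difference, and RSAD2, the antiviral enzyme viperin, fell by 4.39 (SE 0.70, adjusted p = 0.00251). The mean IFIT1 signal was 161 in primed and 2850 in control macrophages, and MX1, a GTPase that blocks viral replication, was 8.53-fold lower. The chemokine CXCL10, a T cell attractant, fell by 4.11 (SE 0.36, adjusted p = 4.28e-06). In contrast, S100A8, a calcium-binding alarmin of monocytes and neutrophils, was 9.91-fold higher in primed macrophages, with a signal of 7110 against 717 (log2 3.31, SE 0.20, adjusted p = 3.54e-08). Its partner S100A9 rose by 2.31 (SE 0.24), and the chemokine receptor CCR2 rose by 3.12 (SE 0.64, adjusted p = 0.0251), with changes of 1.46 and 2.61 in its other probe sets. IFI27 was also higher, by 3.58 (SE 0.40, adjusted p = 5.12e-05), unlike the other antiviral genes named.

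Of 30 measured type I interferon-stimulated genes, 12 fell, 1 rose and 17 were not called, and 16 fell and 1 rose when adjusted over the list alone. Their median change was -1.45 (camera adjusted p = 2.92e-37). In the 3 pools the list median was -1.54, -1.21 and -1.42. Antigen presentation moved the other way. Among 14 genes of MHC class I and the immunoproteasome 3 rose (5 adjusted over the list alone), namely the proteasome subunits PSMB9 (2.27, SE 0.17) and PSMB10 (1.13, SE 0.26) and the peptide-loading protein TAPBP (0.90, SE 0.15), with camera adjusted p = 2.7e-11. Among 14 MHC class II presentation genes 4 rose, HLA-DQA1 by 2.25 (SE 0.32), and 1 fell, the lysosomal protease LGMN, by 1.71 (SE 0.36), a call lost in the values as deposited (-1.20, adjusted p = 0.848); the list was higher (camera adjusted p = 1.08e-05, 5 up and 1 down adjusted over the list alone). Of 23 chemokines 4 fell and none rose, CXCL11 by 2.77 (SE 0.43) and CCL18 by 2.19 (SE 0.46), with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.88e-09). Of 16 genes of Fc receptors and complement 3 rose, 4 adjusted over the list alone, including the IgG receptor FCGR3A (1.21, SE 0.23) and the complement inhibitor SERPING1 (2.34, SE 0.28). That list's adjusted p was 0.0063, and the adjusted p = 0.0747 with an estimated correlation.

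Other lists shifted with few called members. Of 21 immediate early and AP-1 genes 1 rose (4 adjusted over the list alone), EGR3 by 3.43 (SE 0.75), with camera adjusted p = 0.000139. The scavenger receptor and M-CSF macrophage genes had no called member of 28, with 2 higher and 7 lower adjusted over the list alone, and were lower as a list (adjusted p = 0.00196), as were 18 lysosomal genes (0 called, adjusted p = 0.0165). The 22 IFN-gamma effector genes had 1 member higher and 1 lower, 5 and 1 adjusted over the list alone, and adjusted p = 0.00411 upward, with adjusted p = 0.251 with an estimated correlation. Among 21 Toll-like receptor and NF-kB pathway genes 0 were called and 1 was lower adjusted over the list alone, with adjusted p = 0.000217 downward and adjusted p = 0.0717 with an estimated correlation. The 15 sterol genes had 0 called members and adjusted p = 0.0227 upward, with adjusted p = 0.251 with an estimated correlation. No call was made for the lists of JAK-STAT signalling (adjusted p = 0.257), migration receptors (0.104), metalloproteinases (0.257), phagocyte oxidase (0.104), cell cycle (0.944), or metallothioneins and stress genes (0.257). The cytokine list (median -0.007, mean 0.035, tested downward, adjusted p = 0.944) and the apoptosis list (median 0.057, mean -0.111, tested downward, adjusted p = 0.181) gave no call and differed in sign between these measures. Among single regulators of the response, IRF1, a transcription factor induced by IFN-gamma, fell by 0.96 (SE 0.21, adjusted p = 0.0354, and 0.106 in the values as deposited), while IDO1, a tryptophan-degrading enzyme, was at 0.98 (adjusted p = 0.314) and GBP1, a guanylate-binding protein, at 0.59 (adjusted p = 0.762).

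Markers of other blood cells were measured in the same arrays. Of 7 T cell markers 1 fell, IL7R by 2.30 (SE 0.40), a gene that activated monocytes can also express, with adjusted p = 0.000229 and adjusted p = 0.319 with an estimated correlation. The markers of NK cells (adjusted p = 0.23), B cells (0.184), neutrophils (0.491), erythroid cells (0.912) and dendritic cells (0.491) gave no call, nor did those of platelets (0.491), with a median of 0.337, a mean of -0.678 and PPBP at -4.03 (adjusted p = 0.107, 0.045 with the block and 2.53e-05 without pool 2). Without pool 2 limma also called the dendritic cell markers FCER1A (-2.95, adjusted p = 0.000132) and CLEC10A (1.41, adjusted p = 0.0122). It called the neutrophil marker FCGR3B there too (1.01, adjusted p = 0.000553). In pool 2 these 3 genes were at 0.95, 0.81 and -0.36. In all, limma called 43 probe sets higher and 37 lower. With the replicate block the count was 229, and without pools 1, 2 and 3 it was 17, 791 and 22. All 80 calls stood with the block and 78 without pool 2. Here and below, calls kept in these fits are not independent support. With every group in each pool the block leaves fold changes as they are, and the fit without pool 2 reuses arrays of the main fit.

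**Figure D2:**
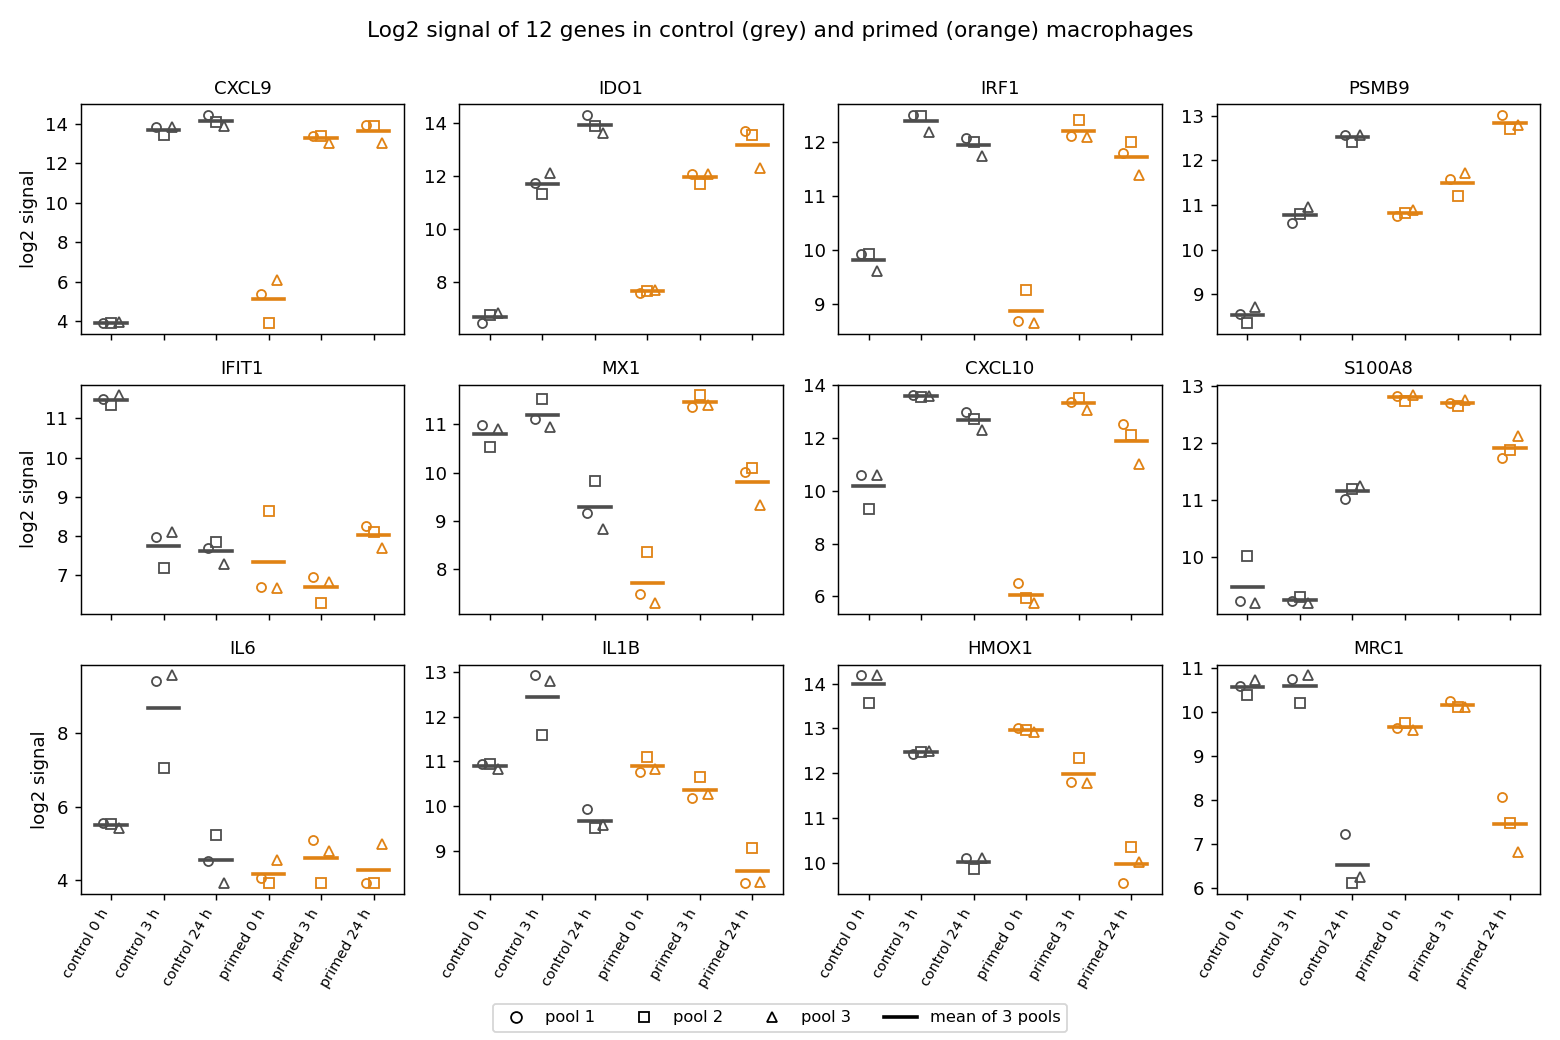
Log2 signal of 12 genes in the 6 groups, 1 symbol per pool and a bar at the mean of the 3 pools, with control macrophages in grey and primed macrophages in orange. IFIT1, MX1 and CXCL10 were lower in primed than in control macrophages at 0 h, while S100A8 and PSMB9 were higher.

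The next comparison asked how control macrophages responded to 3 h of IFN-gamma. The largest rise was that of the chemokine CXCL9, a T cell attractant, with a log2 change of 9.77 (SE 0.39, adjusted p = 6.06e-11); 2 of its 3 unstimulated arrays were at the signal floor, so the rise was at least of that order. CXCL11 rose by 5.37 (SE 0.43) and IDO1 33-fold (log2 5.05, SE 0.30, adjusted p = 1.04e-08). SOCS1, an inhibitor of JAK kinases, rose by 4.86 (SE 0.49), with 2.56 in its other probe set, and GBP1 rose 18.6-fold (log2 4.22, SE 0.24, adjusted p = 5.25e-09). IRF1 rose by 2.56 (SE 0.21, adjusted p = 7.96e-07). The steepest falls were those of the chemokine receptor CXCR4, which fell by 4.35 (SE 0.61, adjusted p = 0.000366), and of IFIT1, which fell by 3.73 (SE 0.45, adjusted p = 6.86e-05) from a signal of 2850 to 215.

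Of 22 IFN-gamma effector genes 12 rose and none fell, 17 adjusted over the list alone, with a median change of 2.0 (camera adjusted p = 3.2e-48). Of 19 JAK-STAT genes 5 rose, 8 up and 1 down adjusted over the list alone, among them IRF8 (1.70, SE 0.31), a transcription factor of macrophage development (adjusted p = 1.03e-07 for the list). Of 23 chemokines 8 rose, 9 adjusted over the list alone, including CXCL10 (3.43, SE 0.36), CCL7 (3.42, SE 0.40) and the monocyte attractant CCL2 (1.56, SE 0.36, not called at 1.10 in the values as deposited), with adjusted p = 5.03e-14. Inflammatory cytokines rose as well, 5 of 20 (7 adjusted over the list alone, adjusted p = 3.6e-05), with IL6 at 3.19 (SE 0.62), TNF at 2.22 (SE 0.29) and IL1B at 1.54 (SE 0.30); the other probe sets of TNF (1.58) and IL1B (1.57) were not called. Of 14 MHC class I genes 4 rose, 5 adjusted over the list alone (adjusted p = 7.2e-07), with the peptide transporter subunits TAP1 at 3.46 (SE 0.43) and TAP2 at 2.97 (SE 0.61). Of 30 type I interferon-stimulated genes 2 rose and 1 fell, 7 and 1 adjusted over the list alone, IFI27 by 3.33 (SE 0.40) and IFI35 by 1.03 (SE 0.20); the list's adjusted p was 0.000139, and adjusted p = 0.101 with an estimated correlation.

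The remaining list calls at 3 h were upward shifts of Toll-like receptor and NF-kB genes (1 of 21 higher, TNFAIP2 by 1.71, SE 0.19, adjusted p = 0.000738, and adjusted p = 0.101 with an estimated correlation), of MHC class II genes (0 of 14, adjusted p = 0.0422, and 0.0944 as adjusted p with an estimated correlation) and of Fc receptors and complement (2 of 16, C1QB by 1.82, SE 0.36, adjusted p = 0.00681, and adjusted p = 0.0944 with an estimated correlation). Adjusted over the list alone, 1 Toll-like receptor and NF-kB gene was higher and 1 lower, 1 MHC class II gene was higher and 2 of Fc receptors and complement were higher. The 5 phagocyte oxidase genes had 0 calls, 1 lower adjusted over the list alone, and adjusted p = 0.0347 downward, with adjusted p = 0.295 with an estimated correlation. CIITA, the master regulator of MHC class II genes, was at 2.33 (adjusted p = 0.096, 0.0235 with the block and 0.0025 without pool 2), and MX1 was at 0.39 and not called. Among metabolic and stress genes, HMOX1, a haem-degrading enzyme, fell by 1.52 (SE 0.21) and the stress gene DDIT4 by 2.80 (SE 0.56). In all, 107 probe sets were higher and 29 lower at 3 h, but 465 and 482 without pool 2 and 262 and 163 with the block, so the balance depended on the setting. The count was 425 with the replicate block and 37, 947 and 39 without pools 1, 2 and 3, with all 136 calls kept with the block and 133 without pool 2. SOCS3, another JAK inhibitor, rose by 3.02 (SE 0.64), and its adjusted p without pool 2 was 0.0569.

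The question of the later comparison was how control macrophages responded over 24 h. CXCL9 stayed the highest, at 10.22 (SE 0.39, adjusted p = 2.84e-11) against unstimulated cells of which 2 arrays were at the floor, and IDO1 rose 155-fold (log2 7.28, SE 0.30, adjusted p = 6.4e-11). The cytokine gene IL32 rose by 7.78 (SE 0.60), the complement factor CFB by 5.40 (SE 0.79) and the secreted glycoprotein CHI3L1 by 4.43 (SE 0.48). The receptor P2RY14 rose by 5.21 (SE 0.49) from a group with all 3 arrays at the floor, a rise of at least that size. The mannose receptor MRC1 fell by 4.04 (SE 0.33, adjusted p = 2.76e-07), the coagulation factor subunit F13A1 by 5.07 (SE 0.63) and the selenium carrier SELENOP by 5.33 (SE 0.68, adjusted p = 5.02e-05). HMOX1 fell by 3.95 (SE 0.21, adjusted p = 9.95e-10), from a signal of 16200 to 1040.

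Antigen presentation rose broadly at 24 h. Of 14 MHC class I and immunoproteasome genes 10 rose and none fell, 10 and 1 adjusted over the list alone (camera adjusted p = 7.4e-13), PSMB9 by 3.97 (SE 0.17). Of 14 MHC class II genes 7 rose and 1 fell, 11 and 1 adjusted over the list alone (adjusted p = 4.37e-08), HLA-DQA1 by 3.03 (SE 0.32), while LGMN fell by 2.92 (SE 0.36). Fc receptors and complement rose in 6 of 16 genes, 7 adjusted over the list alone (adjusted p = 1.48e-05), with C1QB at 4.32 (SE 0.36) and SERPING1 at 4.63 (SE 0.28). The IFN-gamma effector genes rose in 14 of 22 (16 adjusted over the list alone, adjusted p = 3.65e-28), with GBP1 at 4.35 (SE 0.24) and WARS1, a tryptophanyl-tRNA synthetase, at 4.23 (SE 0.30). JAK-STAT genes rose in 5 of 19 (8 adjusted over the list alone, adjusted p = 1.25e-05), IRF1 by 2.12 (SE 0.21). Of 28 scavenger receptor and M-CSF macrophage genes 13 fell and 3 rose, 15 and 3 adjusted over the list alone, with a median of -1.51 (adjusted p = 2.18e-08), with the scavenger receptor STAB1 at -2.65 (SE 0.26) and the matrix protein TGFBI at -2.37 (SE 0.15).

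Several antiviral genes were lower after 24 h than before. Of 30 type I interferon-stimulated genes 3 rose and 6 fell, 4 and 9 adjusted over the list alone, with MX1 at -1.52 (SE 0.31), OASL at -3.63 (SE 0.40) and IFI27 at 5.02 (SE 0.40); the list as such was not called (adjusted p = 0.18). The 23 chemokines split into 4 higher and 7 lower, 4 and 8 adjusted over the list alone, with a median of -0.284, a mean of 0.248 and adjusted p = 0.625 in the downward direction; CCL4 fell by 2.08 (SE 0.26). Of 21 immediate early genes 2 fell, also adjusted over the list alone, IER3 by 1.53 (SE 0.16), with adjusted p = 0.0397, 0.0557 with the block, and adjusted p = 0.248 with an estimated correlation. Of 12 metalloproteinases and inhibitors 3 fell, TIMP1 by 2.27 (SE 0.34) and MMP9 by 1.37 (SE 0.35), and 1 was higher and 3 lower adjusted over the list alone (adjusted p = 0.0273, and adjusted p = 0.0513 with an estimated correlation). IL1B fell by 1.23 (SE 0.30), the receptor TLR2 by 1.14 (SE 0.22) and NFKB1 by 1.26 (SE 0.15). Among other cell types' markers, IL7R fell by 4.24 (SE 0.40) and PPBP, a platelet chemokine, by at least 4.78 (SE 1.04) with 2 of 3 stimulated arrays at the floor and -1.96 in its uncalled other probe set. limma called 246 probe sets higher and 274 lower. The block gave 1262 and kept all 520 calls, and leaving out pools 1, 2 and 3 gave 135, 2289 and 139, with 518 calls kept without pool 2.

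Comparing 24 h directly with 3 h asked which parts of the control response came early and which late. Inflammatory mediators were lower at 24 h than at 3 h. CCL7, a monocyte attractant, fell by 4.88 (SE 0.40, adjusted p = 8.38e-07) between the times, IL6 by 4.13 (SE 0.62, adjusted p = 0.000431, with 1 array at 24 h at the floor), IL1B by 2.76 (SE 0.30, adjusted p = 1.5e-05) and TNF by 2.26 (SE 0.29, adjusted p = 8.87e-05). The feedback inhibitor SOCS3 fell by 3.24 (SE 0.64), whereas SOCS1 was at -0.38 and not called. Late risers included CHI3L1 (4.36, SE 0.48, adjusted p = 1.5e-05), CFB (3.82, SE 0.79) and the lectin LGALS2 (3.87, SE 0.87). The receptor CCR2 rose by 4.12 (SE 0.64), with 2 of 3 arrays at 3 h at the floor, and CXCR4 rose by 3.29 (SE 0.61). LAG3, a receptor that binds MHC class II, rose by 3.28 (SE 0.53) from 3 arrays at the floor, a rise of at least that size. CXCL9 was at 0.45, GBP1 at 0.13 and IRF1 at -0.45, none of them called, though IRF1 had adjusted p = 0.021 with the block.

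By group, 9 of 23 chemokines were lower at 24 h than at 3 h and 1 was higher, 11 and 2 adjusted over the list alone (camera adjusted p = 4.66e-08), with CXCL1 at -3.64 (SE 0.54) and CCL3 at -2.25 (SE 0.19). Toll-like receptor and NF-kB genes fell in 4 of 21, 8 adjusted over the list alone (adjusted p = 2.31e-05), TLR2 by 1.42 (SE 0.22) and NFKB1 by 1.36 (SE 0.15). Cytokines fell in 3 of 20 and rose in 1, 6 and 1 adjusted over the list alone (adjusted p = 0.00776). MHC class I genes rose in 6 of 14 (7 adjusted over the list alone, adjusted p = 8.78e-06), PSMB9 by 1.74 (SE 0.17), and MHC class II genes rose in 6 of 14 and fell in 1 (8 and 2 adjusted over the list alone, adjusted p = 5.33e-05). Fc receptors and complement rose in 6 of 16, 7 adjusted over the list alone (adjusted p = 0.000288). Scavenger receptor and M-CSF macrophage genes fell in 9 of 28 and rose in 3, 12 and 6 adjusted over the list alone (adjusted p = 8.78e-06). Lysosomal genes fell in 4 of 18, including the protease CTSL by 2.46 (SE 0.27), and rose in 2, 6 and 2 adjusted over the list alone (adjusted p = 0.0213).

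Of 30 type I interferon-stimulated genes 5 fell and 1 rose between 3 h and 24 h, 7 and 1 adjusted over the list alone, with MX1 at -1.91 (SE 0.31) and OASL at -4.22 (SE 0.40), and with adjusted p = 2.31e-05 and adjusted p = 0.073 with an estimated correlation. Immediate early genes fell in 4 of 21 and rose in 2, 5 and 3 adjusted over the list alone, with adjusted p = 0.00486 and adjusted p = 0.0955 with an estimated correlation. The phagocyte oxidase list had 1 of 5 genes higher, the subunit CYBA by 0.52 (SE 0.13, not called at 0.42 in the values as deposited), and 2 adjusted over the list alone, with adjusted p = 0.0234 and adjusted p = 0.252 with an estimated correlation. In this comparison 247 probe sets were higher and 254 lower. The share of higher calls was 34.1%, 52.1% and 38.8% without pools 1, 2 and 3. The median of all probe sets was 0.01 after quantile normalization and 0.101 in the values as deposited. The replicate block gave 1411 calls, all 501 among them, and without pools 1, 2 and 3 there were 85, 2597 and 80, with 500 of the 501 called without pool 2.

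**Figure D3:**
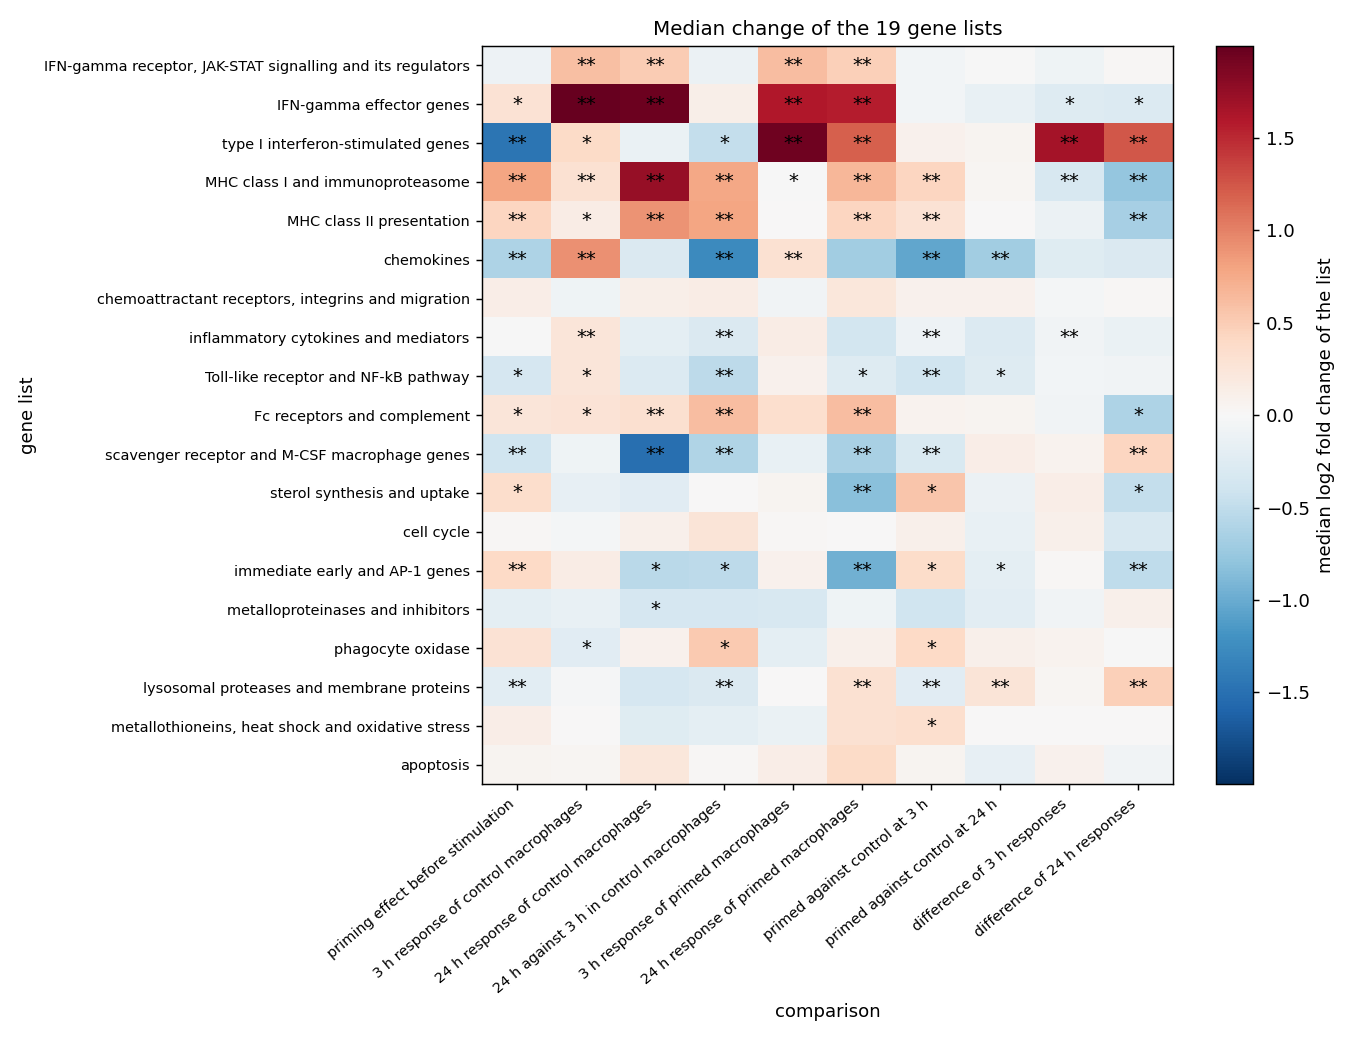
Median log2 fold change (colour) of the 19 gene lists (rows) in the 10 comparisons (columns); 1 asterisk marks an adjusted p under 0.05 in camera with the preset correlation and 2 asterisks mark lists that also had it with an estimated correlation. Type I interferon-stimulated genes had a median of -1.45 in primed macrophages before stimulation and of 1.95 in their 3 h response.

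Primed macrophages were stimulated in the same way, and the next comparison asked for their 3 h response. CXCL9 (8.13, SE 0.39, adjusted p = 1.25e-09, with 1 unstimulated array at the floor), CXCL10 (7.26, SE 0.36, adjusted p = 1.25e-09) and CXCL11 (7.26, SE 0.43) rose most, CXCL10 from a signal of 66.7 to 10200. SOCS1 rose by 6.61 (SE 0.49, adjusted p = 2.03e-07), with 1 unstimulated array at the floor and 1.73 in its other, uncalled probe set. RSAD2 rose by 6.35 (SE 0.70, adjusted p = 3.47e-05) and the death ligand gene TNFSF10 by 4.65 (SE 0.48). MX1 rose 13.5-fold (log2 3.75, SE 0.31, adjusted p = 8.43e-07) and IRF1 10.1-fold (log2 3.34, SE 0.21), while IFIT1 was at -0.65 and not called (0.21 without pool 2). CCR2 fell by 2.69 (SE 0.64, adjusted p = 0.0395) and TGFBR2, a receptor of transforming growth factor beta, by 3.38 (SE 0.58, adjusted p = 0.003); each had 1 stimulated array at the floor, and TGFBR2 was at -2.33 in its uncalled other probe set.

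Of 30 type I interferon-stimulated genes 18 rose and none fell, 23 adjusted over the list alone, with a median of 1.95 (camera adjusted p = 1.07e-47), IFIT3 by 3.82 (SE 0.34) and IFI44 by 2.61 (SE 0.21). IFN-gamma effector genes rose in 14 of 22 (16 adjusted over the list alone, adjusted p = 7.08e-40), with IDO1 at 4.30 (SE 0.30) and GBP1 at 3.30 (SE 0.24). Chemokines rose in 6 of 23, 8 adjusted over the list alone (adjusted p = 1.54e-09), including the monocyte attractant CCL8 by 5.11 (SE 0.47), and JAK-STAT genes rose in 4 of 19, 6 up and 1 down adjusted over the list alone (adjusted p = 6.54e-07). Of 14 MHC class I genes 1 rose, TAP1 by 2.93 (SE 0.43), and 4 adjusted over the list alone; the median was -0.011 and the mean 0.411, with adjusted p = 0.0266 upward and adjusted p = 0.0538 with an estimated correlation. TNF rose by 1.49 (SE 0.29, adjusted p = 0.0105), with 1.20 in its uncalled other probe set. The T cell markers had 0 of 7 called, 1 higher adjusted over the list alone, and adjusted p = 0.0405, which was 0.132 with the block and adjusted p = 0.85 with an estimated correlation. SOCS3 rose by 2.65 (SE 0.64), with adjusted p = 0.118 without pool 2. limma called 122 probe sets higher and 37 lower, but 478 and 640 without pool 2 and 268 and 163 with the replicate block. In total there were 431 with the block and 32, 1118 and 31 without pools 1, 2 and 3. All 159 calls were kept with the block and 156 without pool 2.

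For primed macrophages after 24 h, the question was which of these changes lasted. CXCL9 was at 8.48 (SE 0.39, adjusted p = 6.3e-10, 1 unstimulated array at the floor), SOCS1 at 5.98 (SE 0.49), CXCL10 at 5.82 (SE 0.36) and IDO1 at 5.54 (SE 0.30, adjusted p = 4.79e-09). P2RY14 rose by at least 5.05 (SE 0.49) from 3 arrays at the floor, and IL32 rose by 4.60 (SE 0.60). IER3, an early stress-response gene, fell by 2.85 (SE 0.16, adjusted p = 4.79e-09), F13A1 by 4.58 (SE 0.63, adjusted p = 0.000207) and HMOX1 by 2.99 (SE 0.21, adjusted p = 1.14e-07). The nuclear receptor PPARG fell by 3.49 (SE 0.46, adjusted p = 0.000126), with 2 of 3 stimulated arrays at the floor. IL1B fell by 2.35 (SE 0.30), and TNF fell by 1.26 (SE 0.29), with -0.32 in its uncalled other probe set.

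At 24 h type I interferon-stimulated genes were higher in 14 of 30 than before stimulation and lower in none, 18 and 1 adjusted over the list alone (camera adjusted p = 2.06e-19), MX1 by 2.10 (SE 0.31). The effector genes rose in 13 of 22 (18 adjusted over the list alone, adjusted p = 7.79e-31), JAK-STAT genes in 3 of 19 (7 adjusted over the list alone, adjusted p = 1.94e-06) and MHC class I genes in 5 of 14 (6 adjusted over the list alone, adjusted p = 4.78e-07), with PSMB9 at 2.02 (SE 0.17). MHC class II genes rose in 1 of 14, the peptide-exchange subunit HLA-DMB by 0.89 (SE 0.17), and in 3 with 1 lower adjusted over the list alone (adjusted p = 0.00468). Fc receptors and complement rose in 6 of 16, 6 and 1 lower adjusted over the list alone (adjusted p = 4.72e-06), with C1QB at 3.32 (SE 0.36), and lysosomal genes rose in 2 of 18, 3 adjusted over the list alone (adjusted p = 0.00985). Immediate early genes fell in 5 of 21, 11 adjusted over the list alone (adjusted p = 3.21e-12), with DUSP1, a phosphatase of MAP kinases, at -1.75 (SE 0.29). Scavenger receptor and M-CSF macrophage genes fell in 8 of 28 and rose in 1, 9 and 2 adjusted over the list alone (adjusted p = 5.4e-05), the haemoglobin scavenger receptor CD163 by 2.04 (SE 0.25) with -0.53 in its uncalled other probe set. Sterol genes fell in 1 of 15, INSIG1 by 2.74 (SE 0.51), and in 5 adjusted over the list alone (adjusted p = 0.000102).

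The chemokines had 5 of 23 genes higher and 6 lower, 6 and 8 adjusted over the list alone, with a median of -0.692, a mean of 0.349 and adjusted p = 0.665 downward; CCL4 fell by 2.74 (SE 0.26). Toll-like receptor and NF-kB genes had 1 of 21 higher and 3 lower, 2 and 9 adjusted over the list alone, with NFKB1 at -1.14 (SE 0.15); their adjusted p was 0.0365, 0.0743 with the block, and adjusted p = 0.286 with an estimated correlation. In this response 152 probe sets were higher and 182 lower. The share of higher calls was 41.8%, 48.2% and 60.3% without pools 1, 2 and 3. With the block there were 952, all 334 among them, and 67, 1882 and 73 without pools 1, 2 and 3, with 332 kept without pool 2. The responses of control and primed macrophages shared many genes. At 3 h 68 probe sets were called higher in both, where 1.39 would be shared by chance, and 12 lower (0.114 by chance), and at 24 h 112 were higher (3.98 by chance) and 127 lower (5.31 by chance). These chance figures take the calls as independent. Both responses were tested with the same spread for each probe set, so the figures may be too low. The 246 probe sets called higher in control macrophages at 24 h had a median of 1.86 there and of 1.12 in primed macrophages, and 239 of them had the same sign. Choosing probe sets by one response favours a larger value there. The 152 called higher in primed macrophages had a median of 1.75 there and of 1.69 in control macrophages, and 141 had the same sign.

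**Figure D4:**
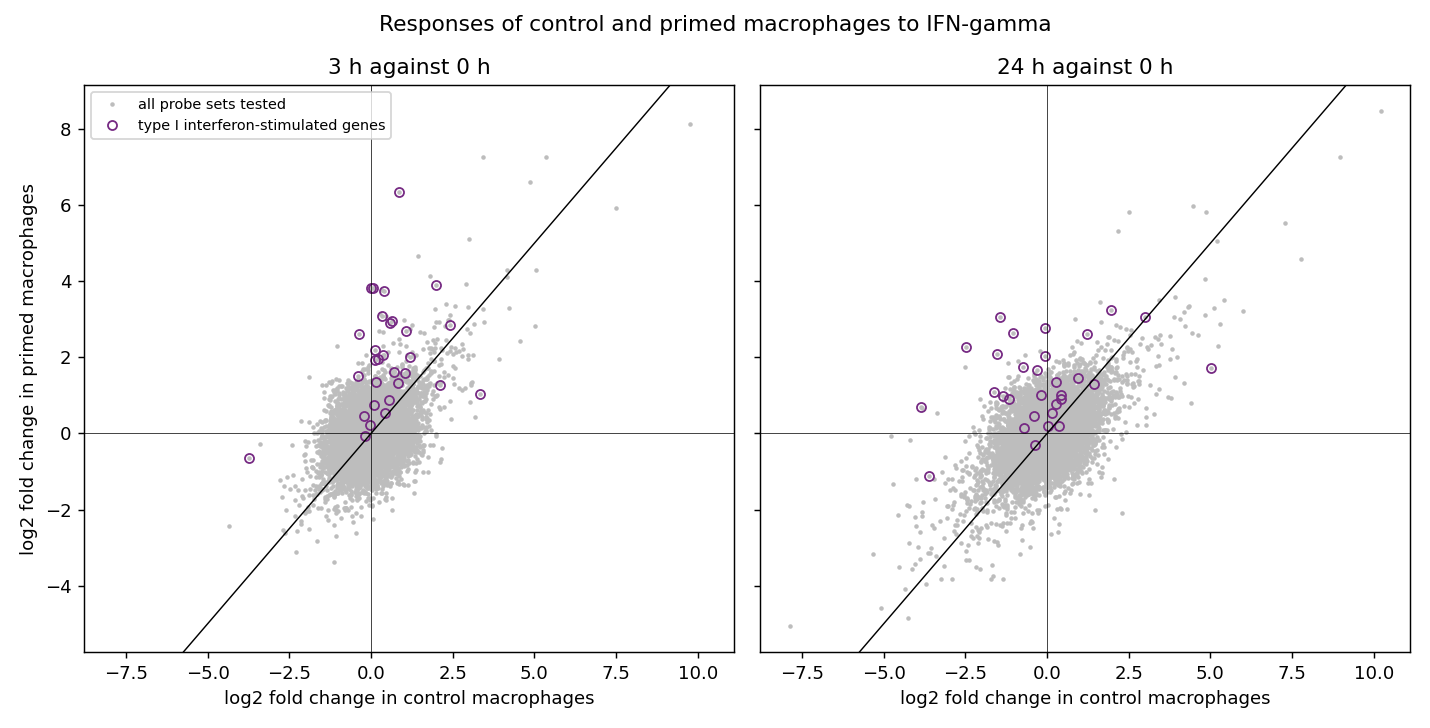
Log2 fold change of each probe set tested in primed (vertical axis) against control macrophages (horizontal axis), after 3 h (left) and 24 h (right) of IFN-gamma, with the diagonal of equal responses. Circles mark the 30 type I interferon-stimulated genes, 18 of which were called higher in primed macrophages at 3 h and 2 in control macrophages.

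Setting primed against control macrophages at the same time of stimulation asked what priming had changed in stimulated cells. At 3 h primed macrophages held less RNA of the inflammatory cytokines IL6 and IL1B. TNF was at -0.74 and not called (adjusted p = 0.619, 0.135 with the block and 0.0914 without pool 2). IL6 was 17-fold lower (log2 -4.09, SE 0.62, adjusted p = 0.00408), with 1 primed array at the floor, and IL1B fell by 2.08 (SE 0.30, adjusted p = 0.00295) to a signal of 1320 against 5570, with -2.15 in its uncalled other probe set. NFKB1, a subunit of NF-kB, was at -0.76 (SE 0.15, adjusted p = 0.03), with other probe sets from -0.90 to -0.76 that were not called, and at -0.56 (adjusted p = 0.664) in the values as deposited. S100A8 (3.45, SE 0.20, adjusted p = 1.85e-08) and S100A9 (2.23, SE 0.24) were higher, as were FBP1, an enzyme of gluconeogenesis (2.66, SE 0.38), and SERPINA1, a protease inhibitor (1.52, SE 0.20, adjusted p = 0.0012). The matrix glycoprotein THBS1 fell by 2.48 (SE 0.37), with -1.88 and -0.53 in its uncalled other probe sets. Among markers of other cells, IL7R fell by 2.38 (SE 0.40, adjusted p = 0.00954), and by 2.99 in its other, called probe set. PPBP was at -3.13 (adjusted p = 0.385, and 2.4e-05 without pool 2), with 2 primed arrays and 1 control array at the floor.

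MHC class II genes were higher in 3 of 14 and lower in 1, 5 and 1 adjusted over the list alone (camera adjusted p = 0.00568), HLA-DQA1 by 1.98 (SE 0.32), and the MHC class I list was higher with 0 of 14 called and 2 adjusted over the list alone (adjusted p = 0.000964). Chemokines were lower as a list with 0 of 23 called, and with 8 lower and 1 higher adjusted over the list alone (adjusted p = 2.28e-11); CCL4 was at -1.20 (adjusted p = 0.0578, 0.00126 with the block and 0.000617 without pool 2). Cytokines had 2 of 20 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0149), and Toll-like receptor and NF-kB genes had 1 of 21 lower, 4 adjusted over the list alone (adjusted p = 4.24e-06), with TLR2 at -1.0 (adjusted p = 0.0578, 0.000294 with the block and 0.000174 without pool 2). Immediate early genes were higher in 2 of 21, JUND by 1.23 (SE 0.21) and IER2 by 1.20 (SE 0.22), 4 up and 1 down adjusted over the list alone, with adjusted p = 0.00153 and adjusted p = 0.0619 with an estimated correlation. Scavenger receptor genes (0 of 28, 2 higher and 3 lower adjusted over the list alone) and lysosomal genes (0 of 18, 1 higher adjusted over the list alone) were lower as lists, each with adjusted p = 0.0215. Upward list calls were lost with an estimated correlation for sterol genes (0 of 15, adjusted p = 0.0157, and adjusted p = 0.194 with an estimated correlation), phagocyte oxidase (0 of 5, 2 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.198 with an estimated correlation) and metallothioneins and stress genes (0 of 22, 1 adjusted over the list alone, adjusted p = 0.0356, 0.0669 with the block, and adjusted p = 0.194 with an estimated correlation). Type I interferon-stimulated genes had 0 of 30 called at 3 h (adjusted p = 0.574). limma called 26 probe sets higher and 14 lower, but 545 and 622 without pool 2 and 121 and 105 with the block. The block gave 226 and kept all 40, and without pools 1, 2 and 3 the counts were 1, 1167 and 2, with all 40 kept without pool 2.

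After 24 h few probe sets were called between primed and control macrophages. IER3 was 2.87-fold lower in primed macrophages (log2 -1.52, SE 0.16, adjusted p = 0.000331), as was CD83, a marker of mature dendritic cells (-1.38, SE 0.20, adjusted p = 0.00722). CCL4, a chemokine for monocytes and T cells, fell by 1.62 (SE 0.26, adjusted p = 0.0152). The actin-bundling protein gene FSCN1 fell by 2.36 (SE 0.37), the costimulatory receptor TNFRSF4 by 2.13 (SE 0.36), LAD1 by 2.79 (SE 0.51) and the transcription factor MSC by 1.62 (SE 0.22). LTA4H, the enzyme that makes leukotriene B4, was the 1 gene higher, by 1.31 (SE 0.20, adjusted p = 0.0139). TNF was at -1.23 (adjusted p = 0.203, 0.026 with the block and 0.0305 without pool 2). IL1B was at -1.13 (adjusted p = 0.414, and 0.000811 without pool 2), and TNFAIP3, an NF-kB inhibitor, was at -0.91 (adjusted p = 0.0565, 0.00341 with the block and 0.00222 without pool 2).

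Chemokines were lower as a list at 24 h with 1 of 23 called and 5 adjusted over the list alone (camera adjusted p = 4.98e-13), and lysosomal genes were higher with 0 of 18 called, 0 also adjusted over the list alone, and a median of 0.26 (adjusted p = 9.67e-05). Toll-like receptor and NF-kB genes had 0 of 21 called and 4 lower adjusted over the list alone (adjusted p = 5.28e-05, and adjusted p = 0.0981 with an estimated correlation), and immediate early genes had 1 of 21 lower, also adjusted over the list alone (adjusted p = 0.00544, and adjusted p = 0.154 with an estimated correlation). Type I interferon-stimulated genes (0 of 30, adjusted p = 0.616) and effector genes (0 of 22, adjusted p = 0.0714) were not called. The split was 1 probe set higher and 7 lower, but 69 and 92 without pool 2 and 21 and 37 with the block. It was 0 and 5 in the values as deposited, where CCL4, LAD1 and LTA4H were not called. With the replicate block there were 58 calls, all 8 among them. Without the intensity trend, or with pools 1 and 3 averaged as 1 sample, limma called 0, with 298 and 120 at an unadjusted p under 0.05. Without pools 1 and 3 limma called 0, with 166 and 121 at an unadjusted p under 0.05, and without pool 2 it called 161, all 8 among them.

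The last question was whether primed macrophages responded to IFN-gamma differently from control macrophages, tested as the difference of the responses. At 3 h the response was larger in primed macrophages for MX1 (log2 difference 3.37, SE 0.44, adjusted p = 0.00209), IFIT3 (3.75, SE 0.48, adjusted p = 0.00209), CXCL10 (3.83, SE 0.51, adjusted p = 0.00211), IFI44 (2.97, SE 0.30, adjusted p = 0.00017), RSAD2 (5.49, SE 0.99, adjusted p = 0.044) and IFIT2 (3.84, SE 0.65, adjusted p = 0.0265). The MX1 signal went from 209 to 2820 in primed and from 1790 to 2340 in control macrophages. Each of these genes was called lower in primed macrophages at 0 h. At 3 h the primed and control signals were 1340 and 2170 for IFIT2 and 10200 and 12400 for CXCL10. They were 5380 and 4920 for IFIT3, 1310 and 935 for IFI44, and 3410 and 1590 for RSAD2. These positive differences thus come largely from the lower primed levels at 0 h. The proteasome subunit PSMB9 responded less in primed macrophages (-1.55, SE 0.25, adjusted p = 0.0149), from 1800 to 2900 against 375 to 1760. Of 30 type I interferon-stimulated genes 5 had a positive and none a negative difference, 15 and 1 adjusted over the list alone, with a median of 1.66 (camera adjusted p = 9.23e-38). MHC class I genes had 1 of 14 with a negative difference, also adjusted over the list alone (adjusted p = 0.00064), and cytokines 0 of 20, 1 adjusted over the list alone (adjusted p = 0.0161). The effector genes had 0 of 22 called, 1 higher and 2 lower adjusted over the list alone, and adjusted p = 0.000169 downward, with adjusted p = 0.293 with an estimated correlation. The split was 7 probe sets higher and 2 lower, 6 and 0 in the values as deposited, but 31 and 38 without pool 2 and 16 and 8 with the block. The block gave 24 calls, all 9 among them, and without pool 2 there were 69, 7 of the 9 among them, with RSAD2 (adjusted p = 0.137) and IFIT2 (adjusted p = 0.101) not called. When pools 1 and 3 were left out in turn limma called 0 probe sets, with 89 and 67 at an unadjusted p under 0.05.

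At 24 h the difference of responses went both ways. Antiviral genes had positive differences, IFIT2 of 4.78 (SE 0.65, adjusted p = 0.00135), IFIT1 of 4.55 (SE 0.63, adjusted p = 0.00153) and MX1 of 3.62 (SE 0.44, adjusted p = 0.000586), and so had GPNMB, a macrophage glycoprotein (1.99, SE 0.36, adjusted p = 0.0136). These differences include a fall in control macrophages, where the IFIT1 signal went from 2850 to 196, against 161 to 258 in primed macrophages. Several genes called higher in primed macrophages before stimulation had negative differences. S100A8 was at -2.55 (SE 0.28, adjusted p = 0.000211), going from 7110 to 3860 in primed and from 717 to 2280 in control macrophages, PSMB9 at -1.96 (SE 0.25, adjusted p = 0.00073) and HLA-DQA1 at -2.60 (SE 0.45, adjusted p = 0.0113). IFI27 was at -3.31 (SE 0.57), SERPING1 at -2.05 (SE 0.39) and the protease inhibitor SERPINA1 at -2.08 (SE 0.28).

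Type I interferon-stimulated genes had 6 of 30 with a positive and 1 with a negative difference, 14 and 1 adjusted over the list alone (median 1.24, camera adjusted p = 4.04e-27). MHC class I genes had 1 of 14 with a negative difference, 4 adjusted over the list alone (adjusted p = 6.94e-09), MHC class II genes 1 of 14, 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.000172), and immediate early genes 1 of 21, 4 adjusted over the list alone (adjusted p = 7.38e-08). Scavenger receptor genes had 1 of 28 with a positive difference, 2 adjusted over the list alone (adjusted p = 0.00111), and lysosomal genes 0 of 18, 2 higher and 1 lower adjusted over the list alone (adjusted p = 4.85e-06). Downward calls lost with an estimated correlation were those of effector genes (1 of 22 lower, 6 and 1 higher adjusted over the list alone, adjusted p = 0.00022), Fc receptors and complement (1 of 16 lower, also adjusted over the list alone, adjusted p = 0.0408, and 0.129 with the block) and sterol genes (0 of 15, adjusted p = 0.00678), each with adjusted p = 0.165 with an estimated correlation. T cell markers had 0 of 7 called, 1 higher adjusted over the list alone, and adjusted p = 0.000165 upward, with adjusted p = 0.148 with an estimated correlation. limma called 11 probe sets higher and 13 lower. With the block there were 124 and without pool 2 there were 350, with all 24 kept in each. Fits without pool 1 or pool 3 called 0 in limma, with 160 and 145 at an unadjusted p under 0.05.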

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

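Tests chosen only after the result was seen were those of the list in single pools, of the list in the values as deposited, all those on the pools, the shares of the top signal and the differences by pool over probe sets that rose, and the count over regroupings that mix the arrays at 0 h. Genes are listed here because their response to IFN-gamma differed between primed and control macrophages in limma's test of the difference. At 3 h the difference was 5.49 for RSAD2, 3.84 for IFIT2, 3.83 for CXCL10, 3.75 for IFIT3, 3.37 for MX1, 2.97 for IFI44 and -1.55 for PSMB9. At 24 h it was 4.78 for IFIT2, 4.55 for IFIT1, 3.70 for IFIT3, 3.62 for MX1, 3.33 for CXCL10, 2.70 for IFI44, 1.99 for GPNMB and 1.97 for OAS2. Negative differences at 24 h were -1.32 for IER3, -1.57 for CD83, -1.64 for MARCKSL1, -1.96 for PSMB9, -2.05 for SERPING1, -2.08 for SERPINA1, -2.55 for S100A8, -2.60 for HLA-DQA1, -3.31 for IFI27 and -4.38 for CYP2B7P, the last with all 3 arrays at the floor in unstimulated control and in primed macrophages at 24 h. All of these kept the same direction in the 3 pools, which is not separate support. The rule for the highest and lowest genes required it, and all 9 calls at 3 h and all 24 at 24 h did so. RSAD2 and IFIT2 at 3 h were not called without pool 2 (adjusted p = 0.137 and 0.101), and none of the 24 h and 3 h calls was made without pool 1 or without pool 3.

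The type I interferon-stimulated genes were lower in primed than in control macrophages before stimulation, with a median of -1.45 over 30 genes. A single pool does not account for this, since the list median was -1.54, -1.21 and -1.42 in the 3 pools (highest -1.21, with 27, 26 and 27 genes below 0). An exchange of the control and primed arrays at 0 h is argued against by the 40 probe sets called at 3 h, of which 97.5% had the same sign before stimulation. Quantile normalization is argued against by the values as deposited, where the list median was -1.44. A candidate explanation that stays open, as a hypothesis, is that cells cultured 48 h with a low dose of IFN-gamma hold back this group of genes, and neither medium nor timing of the cultures was tested. The arrays do not tell whether primed macrophages were low or control macrophages high at 0 h, since no other unstimulated group was measured. The list's median log2 level in control macrophages was 9.93 at 0 h and 10.00 at 3 h, against 8.03 in primed ones at 0 h.

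The arrays of pool 2 stood apart, and limma called 0 probe sets between pools 1 and 3, with 1111 at an unadjusted p under 0.05. The lowest mean spike-in signal of pool 2 was 9.64 times the highest of the other pools, which is consistent with less labelled RNA on its arrays, but also with a different signal range, since its highest signals outside the Affymetrix control probe sets were 128200 to 158400 against 15220 to 19010 elsewhere. Its lowest GAPDH 3' to 5' ratio was 1.2 times the highest elsewhere, which is consistent with a stronger 3' bias of its RNA. The 0 called probe sets between pools 1 and 3 may come from the same RNA on both sets of arrays, but 11.8% of probe sets had an unadjusted p under 0.05, and separate RNA processed alike stays open. Each pool holds all groups, so none of this is confounded with a comparison, and no biological explanation was tested, since the labels do not say how pools differ.

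The third pattern is that the 24 h responses differed in opposite directions, with 11 positive and 13 negative differences, whose sign does not give the size of a response, since some of these genes fell. Signals near the top of the measured range could limit a rise. Averaged over the 3 arrays of primed macrophages at 24 h, the 13 probe sets had a median of 16% and at most 48.2% of the array's highest signal. On single arrays the highest was 72.1%, 13.9% and 58.6% in pools 1, 2 and 3, with 1, 0 and 1 probe sets over 50%. The 8 that rose had a median of 22.3%, with 37.5%, 4.02% and 27% in pools 1, 2 and 3. Their median difference was -2.06 in pool 2, far from its top, against -2.37 and -2.60 in pools 1 and 3. This argues against saturation as the only source of the negative differences, though pool 2 took part in calling these probe sets. Noise in the unstimulated arrays could give such differences. The control ones enter the control response and the primed ones the primed response. Both also enter the priming comparison at 0 h, there with the opposite sign. Of 350 probe sets called without pool 2, 77.7% had the same sign in pool 2 alone, between the 60% and 80% set as limits beforehand. The 3 h and 24 h responses of control and primed macrophages themselves reached only 78.4% to 82.2% by this measure. The test therefore cannot decide, since even these responses hardly pass the upper limit, and that noise stays open. Each difference of responses equals the primed-against-control difference at 24 h minus that at 0 h. At 0 h the 30 type I interferon-stimulated genes had a median log2 level of 9.93 in control and 8.03 in primed macrophages. At 24 h it was 9.38 and 9.48. Their positive differences thus come largely from the levels at 0 h. Other genes still differed at 24 h, such as IER3 and CD83. The hypothesis that 24 h of stimulation brings both kinds of macrophages to similar levels stays open beside that noise for part of the genes.

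The counts were also set against regroupings of the same arrays. For the 8 comparisons between groups of 3, the 10 splits are too few for a share under 0.05. The real counts and the highest other counts were 80 and 1 for priming, 136 and 0 for control macrophages at 3 h, 520 and 0 at 24 h, 501 and 1 for 24 h against 3 h, 159 and 0 for primed macrophages at 3 h, 334 and 0 at 24 h, 40 and 0 for primed against control at 3 h, and 8 and 0 at 24 h. In each, 1 of 10 splits, the real one, gave as many, and 4 of the 10 part every pool as the real one does. For the difference of 3 h responses 7 of 100 regroupings gave at least the real 9, up to 169, and for that of 24 h responses 5 of 100 gave at least the real 24, up to 51. These shares do not measure chance, because every regrouping with as many calls kept the control and primed arrays at 0 h apart, and with them the real priming difference that enters the test. The 91 regroupings that mix the arrays at 0 h gave at most 1 call at 3 h and 4 at 24 h, but mixing arrays that differ also widens the spread, so chance is left open. The regrouping with the highest count exchanges control and primed labels at the stimulated time in all pools, which turns the difference of responses into the sum of the priming differences at both times, and its many calls point to that structure of the samples. Of the 18 regroupings that part every pool, 4 gave at least 9 at 3 h and 2 gave at least 24 at 24 h, and without that exchange the highest others were 10 and 21. Regroupings that part fewer pools reached 25 and 38, again with the priming difference at 0 h intact.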

How the results depend on the processing

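Array quality weights, and pools 1 and 3 averaged as 1 sample, were chosen only after the data were seen; the other alternatives were planned. The counts of called probe sets moved with the pools and with array quality weights. With 1 pool left out, limma called 17 to 791 for the priming effect, 37 to 947 for control macrophages at 3 h, 135 to 2289 at 24 h, 80 to 2597 for 24 h against 3 h, 31 to 1118 for primed macrophages at 3 h, 67 to 1882 at 24 h, 1 to 1167 for primed against control at 3 h, 0 to 161 at 24 h, 0 to 69 for the difference of 3 h responses and 0 to 350 for that of 24 h responses. In every case the highest count was the one without pool 2. Without pool 1 the counts were 17, 37, 135, 85, 32, 67, 1, 0, 0 and 0 in the same order, and without pool 3 they were 22, 39, 139, 80, 31, 73, 2, 0, 0 and 0. Unadjusted p-values under 0.05 beside the 0 counts numbered 166 and 121 for primed against control at 24 h, 89 and 67 for the difference of 3 h responses, and 160 and 145 for that of 24 h responses.

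The replicate block raised the counts to 229, 425, 1262, 1411, 431, 952, 226, 58, 24 and 124, and array quality weights, with a mean of 0.144 in pool 2 against 2.54 and 2.97, to 1277, 1293, 2353, 2426, 1285, 1613, 1294, 126, 166 and 465. Pools 1 and 3 averaged gave 26, 42, 152, 92, 33, 72, 1, 0, 0 and 0, the last 3 with 120, 73 and 148 at an unadjusted p under 0.05. Without the intensity trend 51 were called for priming, 105 for primed macrophages at 3 h, 17 and 0 for primed against control at 3 h and 24 h (298 unadjusted for the latter) and 4 for the difference of 3 h responses. The values as deposited gave 5 for primed against control at 24 h, and no filter gave 14 there and 5 for the difference of 3 h responses.

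Of 206 named gene values, 108 were the same without pool 1, 192 without pool 2, 112 without pool 3 and 199 with the block, which made 7 more calls and changed no other call. Directions turned for 3 genes, none of them called. SOCS1 at 24 h against 3 h (-0.38) ranged from -0.72 without pool 1 to 0.20 without pool 3. GBP1 there (0.13) ranged from -0.023 without pool 1 to 0.24 without pool 3 and was -0.007 in the values as deposited. IFIT1 in primed macrophages at 3 h (-0.65) ranged from -1.11 without pool 1 to 0.21 without pool 2 and was 0.14 with array quality weights. Of 84 calls of pathway lists over the 10 comparisons, 58 stayed called with the estimated correlation and 80 with the block. Marker lists are not in this count. The cause of these changes was not tested. Probe sets near the background limit what can be said, because changes below the floor of 15.1 are not measured.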

Other observations

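The genes and levels of the first paragraph were chosen only after the values were seen, and the test of fading was set before its own result was computed, but after the counts of called probe sets were known. In control macrophages the median log2 level of the 30 type I interferon-stimulated genes was 9.93 at 0 h, 10.00 at 3 h and 9.38 at 24 h, and in primed macrophages 8.03, 10.21 and 9.48. The list of 22 metallothionein, heat shock and oxidative stress genes was not called in the 3 h or 24 h response of control macrophages (camera adjusted p = 0.986 and 0.826) or of primed ones (0.528 and 0.264), and its single genes moved in both directions. TXN rose by 1.20 at 3 h in control macrophages (adjusted p = 0.0105) and by 1.05 in primed ones (adjusted p = 0.0275), and stood 1.12 higher at 24 h in primed ones (adjusted p = 0.00899). Its reductase TXNRD1 changed by -1.89 in control and -1.48 in primed macrophages at 24 h (adjusted p = 5.92e-06 and 0.000153), and NQO1 by -1.85 and -1.23 (adjusted p = 0.00105 and 0.0378). MT1X was higher by 2.44 in primed macrophages before stimulation (adjusted p = 0.0425) and by 2.96 at 24 h against 3 h in control macrophages (adjusted p = 0.00256). Several of these were called only by some settings. TXN was not called in any of its 3 comparisons in the values as deposited, without the intensity trend or without pool 1. MT1X and NQO1 were not called without pool 1 or without pool 3, while every direction stayed the same.

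The difference made by priming may fade during stimulation. Of the 791 probe sets called for priming without pool 2, the median difference in pool 2, signed by the direction in the other pools, was 0.38 before stimulation, 0.32 at 3 h (85.2%) and 0.04 at 24 h, or 9.52% of that before stimulation. Pool 2 had no part in the choice of these probe sets, so noise in that choice does not account for the fading. The probe sets were still chosen by their difference at 0 h, so smaller differences at other times can come from this choice. Probe sets that differed only after stimulation were left out by it. A weaker signal of pool 2 as a whole could also lower all 3 values. The cause of this course was not tested. The sign in pool 2 matched that of the other pools for 71.8% of probe sets called for priming, 61.7% for primed against control at 3 h, 78.3% at 24 h, 79.5% and 81.6% for the 3 h and 24 h responses of control macrophages, and 78.4% and 82.2% for those of primed ones. Functional state of the cells was not measured, and whether the genes named here matter for it is a hypothesis open to test in further pools.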
